A study of Mus musculus with 8 samples.

How the data were processed

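Expression was measured in liver from 4 mice with a transgene for constitutively active IKK2 and from 4 control mice, all 4 weeks old, on 8 Affymetrix arrays. Per the labels, total RNA from frozen liver was turned into biotin-labelled sense targets covering whole transcripts, and the mice came from a mixed stock of C57BL/6 and NMRI that had been backcrossed to C57BL/6 at least 4 times. The deposited values are log2 expression values, 1 per probe set and array, made with Affymetrix Expression Console per the submitters' processing notes. Its version, its settings and the normalization method are not given in the sources used here. That the scale is base 2 was read from the values themselves, whose maximum of 14.1 is above what a natural logarithm of a 16-bit scanner reading allows. Array medians lie between 4.88 and 5.08 and upper quartiles between 6.76 and 7.06. Under a rule fixed before, this was taken as near enough to apply no further normalization, a choice that matters: quantile normalization moves the number of lower genes from 333 to 638. Scanner files and detection p-values were not used here, so signal could not be set against background, and the number of arrays limits the precision.

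The deposited data hold 35556 probe sets. Annotation ties 21789 of them to 1 gene symbol, 1621 to several and 12146 to none, and only the first kind entered the tests. Entrez identifiers of 21698 matched the reference table of the assembly GRCm38.p6, which was used for names alone and changed 0 symbols. Limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8) fitted a linear model with the group as its only term to all 21789, followed by empirical Bayes moderation (prior degrees of freedom 3.77). The tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the 21789 probe sets, and a probe set passed at an adjusted p under 0.05. Genes were then counted once, through the probe set with the highest mean over all 8 arrays, which gave 19938 genes. There were 999 genes with more than 1 probe set. Of the called genes 67 were among them, of which 14 had a probe set with the opposite sign and 0 a called one. Log2 fold changes are transgenic minus control, and SE is limma's standard error.

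The 40 lists, 26 of gene functions and 14 of cell types, hold 852 entries, of which 776 were measured. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one, with fry beside it, and adjusted over the 40 lists. For each list the members past the threshold were counted over all genes and again adjusted over the list alone. Lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. That rule names Ikbkb, the 10 highest and the 10 lowest log2 fold changes among called genes whose groups do not overlap, the 2 called members with the largest changes of each list (or the member with the smallest p), and the genes of the sex chromosomes. Gm21286, a predicted gene among the 10 lowest, was not named, as the rule sets. Outside the rule, 16 further genes were chosen after their values were seen, the remaining members of counts of 5 or fewer (Tgfb1, Il1b, Vegfa, Herc6, Nr0b2, Abcg5, Tm7sf2, Foxa1, Nudt7, Selenbp2, Zap70, Clec9a, Itgae, Pdgfra, Dcn and Gata1). Socs2, also outside the rule, served a test set before its value was seen.

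The same steps were tested on simulated data with the real genes' means and spreads. Among 19938 genes limma recovered 50 of 50 genes changed by a log2 fold change of 2, 50 of 50 at -2, 44 of 50 at 1 and 45 of 50 at -1, with 13 false calls. A cell cycle list moved on purpose passed camera (adjusted p = 4.44e-17) and 0 other lists did. With no change simulated, 0 genes and 0 lists passed. The simulated genes varied independently of each other, so the simulation cannot show how camera behaves when genes of a list vary together.

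Alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 30% or 50% of probe sets, testing all deposited probe sets, averaging a gene's probe sets, moderation with trend and robust options, array weights, the replicate number as a block, limma's treat against a 1.2-fold change, and leaving out each array in turn. For the lists an estimated correlation and the removal of genes standing in more than 1 list were added. An alternative pseudocount, planned for linear values, did not apply to log2 values.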

Results

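Gene expression was measured in the livers of 4 transgenic mice, which carry a constitutively active form of the kinase IKK2 behind the LAP promoter, and of 4 control mice. All were 4 weeks old, and each liver has its own array, giving 8 arrays with 1 log2 expression value per probe set. Array medians lay between 4.88 and 5.08. The labels call the 4 arrays of a group biological replicates, so the p-values measure differences against the spread between these animals. The number of arrays limits the precision, and no background was measured.

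IKK2, the product of the gene Ikbkb, phosphorylates the inhibitors that hold the transcription factor NF-kB in the cytoplasm. NF-kB drives genes of inflammation, of immune cell recruitment and of cell survival. The LAP promoter is active in hepatocytes, the main cells of the liver. The comparison asks which transcripts of the whole organ differ when this kinase is switched on in its hepatocytes.

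The gene of the kinase itself was higher in every transgenic liver. Ikbkb (probe set 10577560) read 8.995, 9.09, 8.38 and 8.38 in transgenic replicates 1 to 4, and 7.79, 7.44, 7.85 and 7.77 in the controls. Its log2 fold change was 1.00 (2.00-fold, SE 0.18, adjusted p = 0.0185). Whether this probe set reads the transgene as well as the mouse's own gene is not given in the sources used here. The call was lost without transgenic replicate 1 (adjusted p = 0.0688) and without control replicates 1, 2, 3 or 4 (0.0546, 0.0691, 0.0565 and 0.0566), and in limma's treat test against a 1.2-fold change (0.0729), over a range of 0.00964 to 0.0729 in all settings tried.

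Of 19938 genes tested, 932 were higher and 333 lower in transgenic liver, together 6.34%. By at least 2-fold, 485 were higher and 34 lower. Higher genes made up 73.7% of the calls, 62.6% after quantile normalization and 86.4% with each array centred on its median, so the balance of both directions depends on the scaling. At an unadjusted p under 0.05, 6701 genes passed. The groups did not overlap for 1255 of the 1265 called genes and for 22.4% of all genes, against 2.86% by chance. The counts depend on which arrays are kept. Without transgenic replicate 1, 199 genes were higher and 3 lower, whereas 977 were higher and 260 lower without transgenic replicate 2. Without replicates 3 or 4 of that group the counts were 1359 and 675, or 1636 and 944. Without control replicates 1, 2, 3 or 4 the numbers were 256 and 13, 192 and 10, 203 and 35, or 268 and 32.

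**Figure D1:**
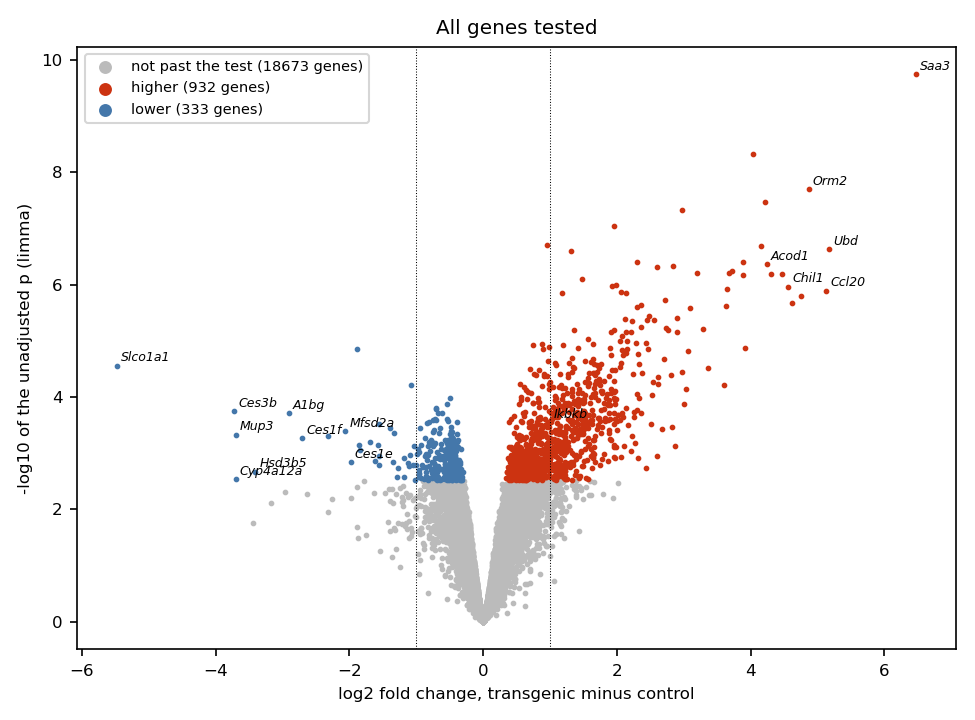
Log2 fold change of each gene, transgenic minus control (x axis), against -log10 of its unadjusted p from limma (y axis); each point is 1 gene, and dotted lines mark 2-fold. The 485 genes higher by at least 2-fold reach further and outnumber the 34 lower ones.

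The 10 highest log2 fold changes belonged to genes of several functions. Saa3 (probe set 10563597), a serum amyloid A of the acute phase, rose 88.8-fold, a log2 fold change of 6.47 (SE 0.24, adjusted p = 3.93e-06). Ubd, a ubiquitin-like protein induced by inflammatory cytokines, rose by 5.17 (SE 0.41, adjusted p = 0.000541). The chemokine Ccl20, which attracts dendritic cells and lymphocytes, rose by 5.13 (SE 0.49, adjusted p = 0.00103). The plasma glycoprotein Orm2 rose by 4.87 and the amyloid Saa1 by 4.75. Guca2b, a peptide ligand of guanylate cyclase, rose by 4.62. Chil1, a chitinase-like secreted protein, rose by 4.56, and the chemokine Ccl5 by 4.47. Ms4a4a, a membrane protein of macrophages, rose by 4.30, and Acod1, the enzyme that makes itaconate in activated macrophages, by 4.24. Controls read 3.69 to 4.21 for Ubd, 4.06 to 4.50 for Ccl20, 4.16 to 4.63 for Ms4a4a and 4.31 to 4.78 for Acod1. These readings lie under every array median, so the sizes of those rises are uncertain. The 10 genes were higher in all 4 transgenic arrays than in any control, which the rule for naming them requires. They kept their calls in every setting tried.

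The lowest log2 fold changes included those of transporters, enzymes and secreted proteins. The organic anion transporter Slco1a1 (probe set 10548978) fell by 5.47 on the log2 scale (SE 0.74, adjusted p = 0.00651). Transgenic replicate 4 read 5.54 for it, against 3.46 to 3.79 in the other transgenic arrays. The latter are near Xist, a transcript of females that read 2.95 to 3.39 in all 8 arrays, so the size of this fall is uncertain. The carboxylesterases Ces3b, Ces1f and Ces1e, which split esters of lipids and drugs, fell by 3.72, by 2.70 and by 1.98, the fall of Ces3b with an adjusted p = 0.0158. Mup3, a urinary protein made in the liver, had a log2 fold change of -3.70 (adjusted p = 0.0235). The fatty acid hydroxylase Cyp4a12a also stood at -3.70 (SE 0.94, adjusted p = 0.0496), with transgenic replicates 1 to 3 at 4.24, 3.68 and 4.23. The steroid dehydrogenase Hsd3b5 stood at -3.41, with a transgenic mean of 3.71. Such low readings make the sizes of both falls as uncertain. A1bg, a plasma glycoprotein, stood at -2.91, with control replicate 1 at 7.51 and the other controls at 9.11 to 9.42. Mfsd2a, a lysophospholipid transporter induced by fasting, fell by 2.06. All 9 were lower in every transgenic array than in any control, as the same rule requires. Of these only Slco1a1 was called in every setting.

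**Figure D2:**
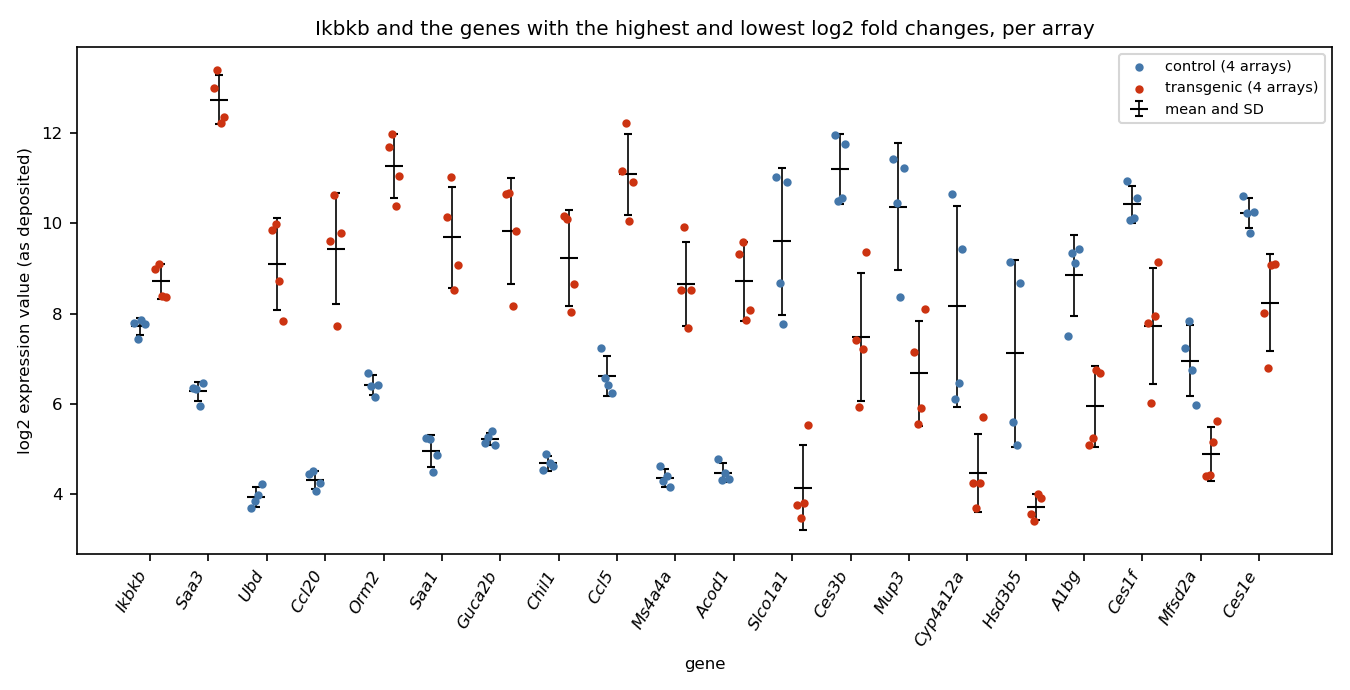
Log2 expression value (y axis) in each of the 4 control and 4 transgenic arrays for Ikbkb and the genes with the highest and lowest log2 fold changes (x axis); points are arrays, and bars are the mean and SD of a group. Saa3 lies between 12.2 and 13.4 in the transgenic arrays, while the falling Cyp4a12a and Hsd3b5 spread widely among the controls, with SDs of 2.23 and 2.07.

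Groups of genes were read through 40 lists fixed before the values were seen. With its preset correlation of 0.01, limma's camera called 18 lists higher and 7 lower. With an estimated correlation it called 0, at a smallest adjusted p of 0.153. In addition, 4 of the 35 splits of the 8 arrays into 4 and 4, the real one included, gave at least 25 lists. Other splits can keep part of the group difference, so this share does not measure chance alone. The list calls below therefore rest on the preset correlation, while the counts of members rest on the genes' own tests. Fry, which tests whether a list moves one way and does not compare it with other genes, called 12 lists up and 2 down. The 2 were the pancreatic acinar and the mesothelium and adipose lists (adjusted p = 0.0413 and 0.0177). Of their members, 3 of 10 and 3 of 8 read above the median of all genes in the controls. With genes put into 4 groups by mean level, the 2 dimmer groups had median log2 fold changes of -0.10 and -0.17 as deposited. The 2 brighter groups stood at 0.04 and 0.06. Fry's calls therefore do not separate these lists from dim genes at large. Fry did not call the other 6 lists that camera called lower (adjusted p from 0.0665 to 0.102), nor 6 that camera called higher. Those were the interferon, IKK and endothelial lists (each 0.125), oxidative stress (0.102), stellate cells (0.0733) and the cell cycle (0.0517).

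Genes that NF-kB switches on, many of which feed back on it, had the smallest camera p of the 40 lists. Of 33 measured, 22 rose, 0 fell and 11 did not pass, and 29 rose adjusted over the list alone. All 33 fold changes were positive, with a median of 1.19 (camera adjusted p = 1.57e-21; adjusted p = 0.214 with an estimated correlation). Tnfaip3, the enzyme A20 that ends NF-kB signalling, rose by 3.28, and Icam1, an adhesion molecule for leukocytes, by 2.71. The list's mean was 6.56 in control replicate 1 and 6.490 to 6.498 in the other controls. Which cells carry the NF-kB transcripts was not tested, and Kupffer cell and monocyte markers were higher in the same livers (medians 1.42 and 1.57). Of 12 genes of the IKK complex and of the signalling upstream of it, 10 were measured, without Chuk and Ripk1. Only Ikbkb rose over all genes, and 3 rose adjusted over the list alone. The median was 0.15 (camera adjusted p = 0.0173; adjusted p = 0.495 with an estimated correlation), and the call was lost without transgenic replicate 2 (adjusted p = 0.0689). It was also lost after quantile normalization (0.135), without the dimmest 30% or 50% of probe sets (0.0776 and 0.0952) and with array weights (0.0983).

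Chemokines recruit leukocytes into tissue. In this list 10 of 28 rose, 0 fell and 18 did not pass, and 13 rose adjusted over the list alone, Ccl20 and Ccl5 the most. The median was 0.66 (camera adjusted p = 3.42e-08; adjusted p = 0.159 with an estimated correlation). Among 28 cytokines and growth factors 5 rose and 1 fell; adjusted over the list alone 9 rose and 3 fell. The death ligand Tnfsf10 rose by 2.00 and the macrophage growth factor Csf1 by 1.68. Tgfb1, Il1b and Hgf rose by 1.17, 0.97 and 0.74, and the angiogenic factor Vegfa fell by 0.52. Their list's median was only 0.07 (camera adjusted p = 0.0334; adjusted p = 0.214 with an estimated correlation). Its call was lost without control replicate 1 (adjusted p = 0.0648), without the dimmest 50% of probe sets (0.215) and when genes standing in more than 1 list were left out (0.232).

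Interferons induce antiviral genes and the machinery that presents antigens to T cells. Of 20 interferon-stimulated genes 3 rose, 0 fell and 17 did not pass, and 6 rose adjusted over the list alone. The 3 past over all genes were the GTPase Gbp3 at 2.25, the antiviral Ifit2 at 2.21 and the ubiquitin ligase Herc6 at 1.198. The median was 0.72 (camera adjusted p = 1.78e-06; adjusted p = 0.489 with an estimated correlation). Of 11 genes of MHC class I and the immunoproteasome 6 rose, 0 fell and 5 did not pass, or 10 rose adjusted over the list alone. The protease subunit Psmb8 rose by 1.61 and the class I gene H2-Q4 by 1.54. The median was 0.91 (camera adjusted p = 4.55e-07; adjusted p = 0.282 with an estimated correlation), and the list's mean was 8.55 in control replicate 1 against 8.40 to 8.42 in the other controls. MHC class II presentation had the highest median of all lists, 1.99 (camera adjusted p = 6.38e-11; adjusted p = 0.159 with an estimated correlation). There 7 of 9 rose and 8 did adjusted over the list alone. Macrophages and dendritic cells bear class II molecules, and markers of Kupffer cells, monocytes and dendritic cells had medians of 1.42, 1.57 and 0.48. Whether these cells were more numerous was not tested. The invariant chain Cd74 rose by 4.16 (SE 0.33, adjusted p = 0.000541) and the class II chain H2-Ab1 by 3.65.

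Acute phase proteins are released by hepatocytes in response to cytokines. Of 29 measured, 13 rose, 0 fell and 16 did not pass. Adjusted over the list alone 17 rose and 1 fell. The median was 0.57 (camera adjusted p = 2.21e-11; adjusted p = 0.153 with an estimated correlation). Saa3 and Orm2 led the list. Complement and coagulation factors, made by the same cells, did not move as a group: the median of 28 was -0.16 (camera adjusted p = 0.251). Only the complement protease C2 rose, by 1.23, also adjusted over the list alone. This list's mean was 10.1 in transgenic replicate 2 and 10.5 in the other transgenic arrays, and it passed as lower without control replicate 2 (adjusted p = 0.0288) and without the dimmest 50% of probe sets (0.0158).

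**Figure D3:**
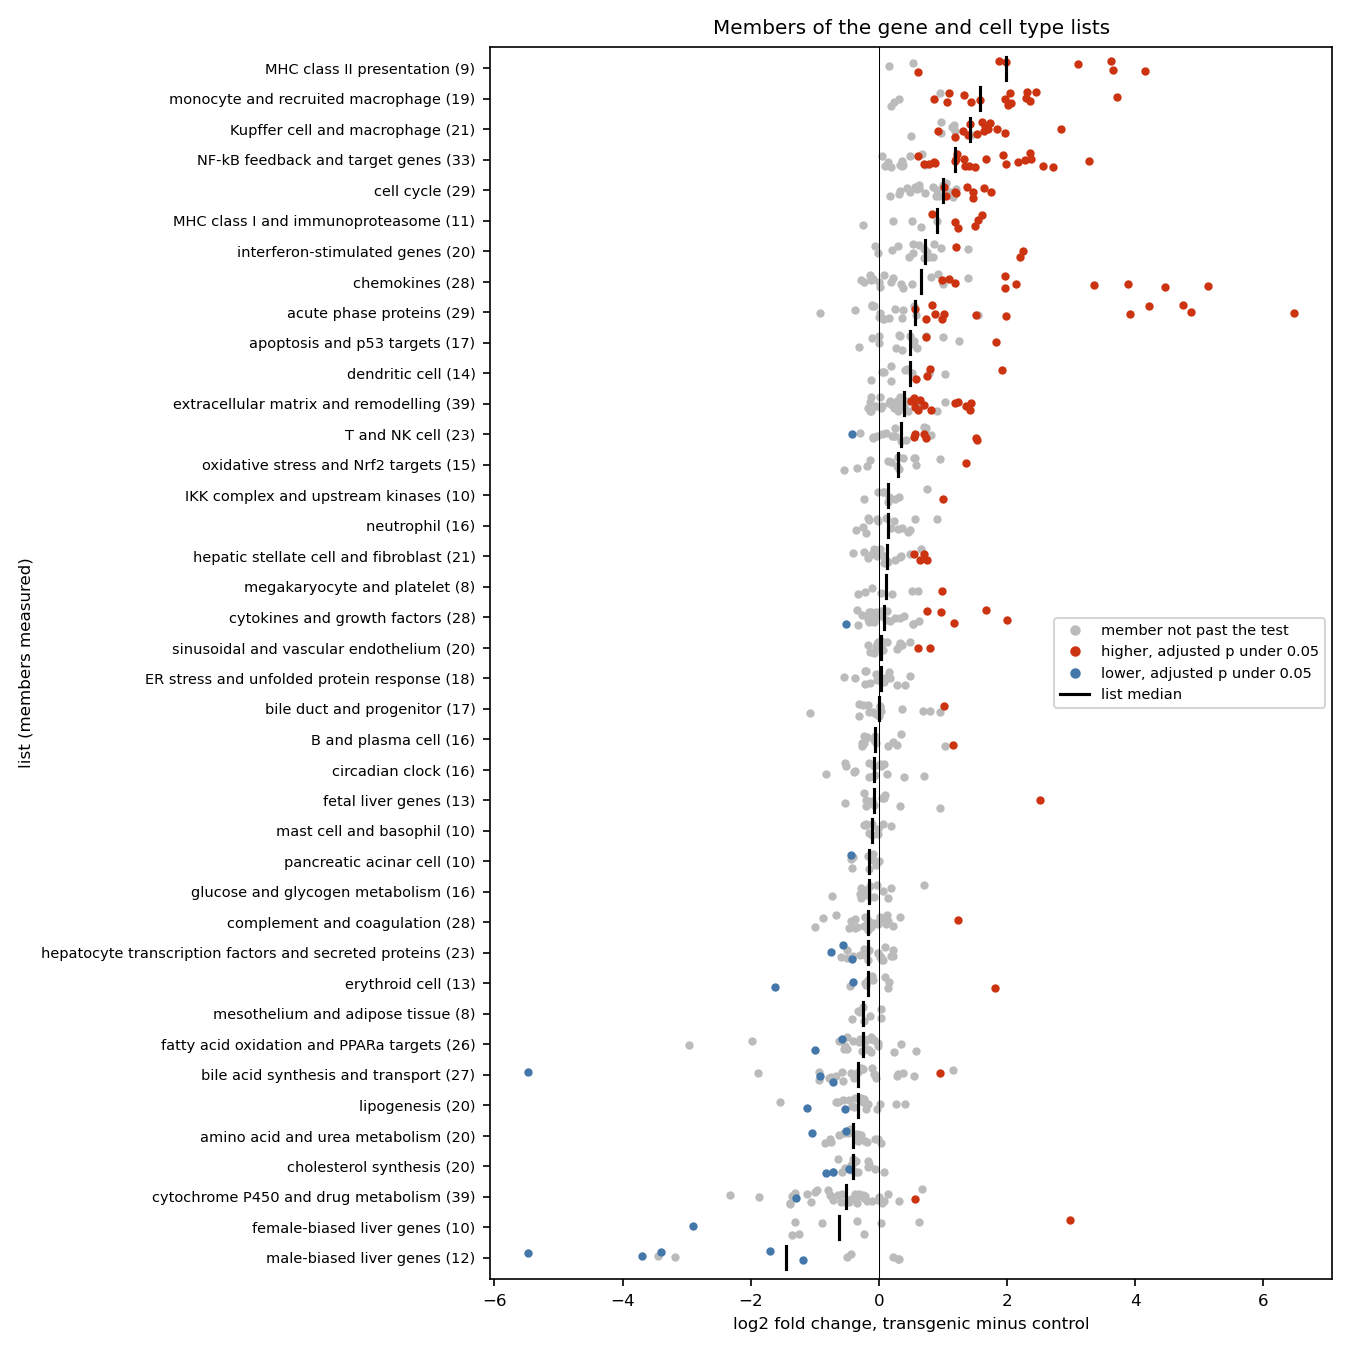
Log2 fold change of each list member, transgenic minus control (x axis), for the 40 lists (y axis, members measured in brackets); points are genes, coloured by call, and black bars are list medians. Medians run from 1.99 for MHC class II presentation to -1.44 for male-biased liver genes.

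Transcripts that mark macrophages were higher, both those of the resident Kupffer cells and those of recruited monocytes. Of 21 Kupffer cell and macrophage genes 14 rose and 7 did not pass, and all 21 rose adjusted over the list alone. The median was 1.42 (camera adjusted p = 3.17e-17; adjusted p = 0.282 with an estimated correlation). The lysozyme Lyz2 rose by 2.84 (SE 0.24, adjusted p = 0.000697) and the antibody receptor Fcgr1 by 1.96. Of 19 monocyte genes, 15 rose and 4 did not pass, and 17 rose adjusted over the list alone, with a median of 1.57 (camera adjusted p = 1.41e-15; adjusted p = 0.159 with an estimated correlation). Ccr2, the receptor that draws monocytes from blood, rose by 3.72 and the integrin Itgax by 2.46. Controls read 3.69 to 3.98 for Ccr2. These and the control readings of Itgax lie under every array median, so the sizes of both rises are uncertain. Neutrophil genes gave a median of 0.15 (camera adjusted p = 0.251). Of 16, 0 passed limma's test, also adjusted over the list alone; Ltf, the member with the smallest p, stood at 0.23 (adjusted p = 0.127). Without transgenic replicate 1 the neutrophil list passed as higher (adjusted p = 0.0470).

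Lymphocytes and dendritic cells carry out and start adaptive immune responses. Among 23 T and NK cell genes 6 rose and 1 fell; adjusted over the list alone 11 rose and 2 fell. The T cell receptor component Cd3g rose by 1.53 and the granule protein Nkg7 by 1.52, whereas the kinase Zap70 fell by 0.42. The median was 0.34 (camera adjusted p = 2.27e-05; adjusted p = 0.306 with an estimated correlation), and the list's mean was 5.41 in transgenic replicate 2 against 4.90 to 4.98 in the other transgenic arrays. Dendritic cell genes had a median of 0.48 (camera adjusted p = 5.67e-06; adjusted p = 0.159 with an estimated correlation). The lectin Cd209a rose by 1.92, the growth factor receptor Flt3 by 0.80, Clec9a by 0.75 and Itgae by 0.58. Clec9a read 5.19 in transgenic replicate 2 and 4.33 to 4.43 in the other transgenic arrays. These 4 of 14 passed over all genes, and 8 rose adjusted over the list alone. The dendritic call was lost without the dimmest 50% of probe sets (adjusted p = 0.215). For B and plasma cells the signs differed, with a median of -0.06 over 16 genes, a mean of 0.10 and camera's direction up (adjusted p = 0.698). The median was 0.02 under both other scalings. Only the scaffold protein Bank1 rose, by 1.16, also adjusted over the list alone.

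Extracellular matrix in the liver is made largely by stellate cells and fibroblasts. Of 39 matrix and remodelling genes 13 rose, 0 fell and 26 did not pass, and 20 rose adjusted over the list alone. The median was 0.39 (camera adjusted p = 3.73e-11; adjusted p = 0.159 with an estimated correlation). The macrophage elastase Mmp12 rose by 1.44 and the adhesion protein Tgfbi by 1.42. The mean of this list was 7.15 in transgenic replicate 3 and 7.25 to 7.27 in the other transgenic arrays. Stellate cell and fibroblast genes had a median of 0.13 (camera adjusted p = 0.0038; adjusted p = 0.338 with an estimated correlation). In this list of 21, of which 5 also stand in another list, 4 rose and 5 did adjusted over the list alone. They were the hepatocyte growth factor Hgf at 0.74, the collagen Col1a1 at 0.71, the receptor Pdgfra at 0.64 and the proteoglycan Dcn at 0.55. The stellate call was lost without genes of more than 1 list (adjusted p = 0.226), without the dimmest 50% of probe sets (0.129) and after quantile normalization (0.0645), where the median was 0.0042. The endothelial median was 0.03 (camera adjusted p = 0.0119; adjusted p = 0.489 with an estimated correlation) and turned to -0.05 after quantile normalization. The scavenger receptor Stab1 rose by 0.80 and the sialomucin Cd34 by 0.61, and 5 of 20 rose adjusted over the list alone. The endothelial call was lost without transgenic replicate 3 (adjusted p = 0.0603) and without control replicate 2 (0.0530). Quantile normalization (0.246), leaving out the dimmest 30% or 50% (0.0808 and 0.333) and array weights (0.0606) ended it as well.

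Other cell types gave few calls. Bile duct and progenitor genes had a median of -0.00267, a mean of 0.09 and camera's direction up (adjusted p = 0.588), with the median at 0.08 after centring on array medians. Of 17, the annexin Anxa5 rose, by 1.02, over all genes and adjusted over the list alone. Erythroid genes had a median of -0.18 (camera adjusted p = 0.345). The transferrin receptor Tfrc rose by 1.81, the carbonic anhydrase Car1 fell by 1.62 and the transcription factor Gata1 fell by 0.40, the same 1 and 2 of 13 as adjusted over the list alone. Car1 read 4.99 in transgenic replicate 2 and 6.48 to 6.79 in the other transgenic arrays. The megakaryocyte and platelet list had a median of 0.12 (camera adjusted p = 0.226); the platelet chemokine Pf4 rose by 0.98, and adjusted over the list alone 2 of 8 rose and 1 fell. Mast cell and basophil genes stood at -0.11 (camera adjusted p = 0.471) and the protease Tpsb2 at -0.23 (adjusted p = 0.124). Limma's test called 0 of those 10, also adjusted over the list alone. Pancreatic acinar genes, a check for neighbouring tissue, had a median of -0.16 (camera adjusted p = 0.0416; adjusted p = 0.489 with an estimated correlation). That median lies between the -0.10 and -0.17 of the 2 dimmer groups of all genes. The elastase Cela1 fell by 0.43, and adjusted over the list alone 2 of 10 fell. Their call was lost without transgenic replicates 1 or 2 (adjusted p = 0.0536 and 0.0584) and without control replicates 2 or 3 (0.0510 and 0.0583), as well as after quantile normalization (0.228) and with array weights (0.0824). For mesothelium and adipose tissue the median was -0.24 (camera adjusted p = 0.102). Of 8 members limma's test called 0 over all genes and 1, lower, adjusted over the list alone, with Upk1b at -0.42 (adjusted p = 0.0540).

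Dividing cells transcribe genes of DNA replication and mitosis. Of 29 cell cycle genes 9 rose, 0 fell and 20 did not pass, while 24 rose adjusted over the list alone and all 29 fold changes were positive. The median was 1.00 (camera adjusted p = 1.13e-13; adjusted p = 0.325 with an estimated correlation). The mitotic checkpoint kinase Bub1 rose by 1.75 and the DNA topoisomerase Top2a by 1.64. Which cells of the liver carry these transcripts was not tested, and macrophage and monocyte lists were higher in the same animals. Apoptosis genes and p53 targets, read as 1 list, had a median of 0.49 (camera adjusted p = 6.65e-05, and adjusted p = 0.325 with an estimated correlation). There 2 of 17 rose, and 8 did adjusted over the list alone. Mlkl, the effector of necroptosis, rose by 1.82 and the death receptor Fas by 0.73.

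Oxidative stress and misfolded proteins each switch on a programme of their own. Of 15 genes of oxidative stress the haem oxygenase Hmox1 rose, by 1.36, and adjusted over the list alone 5 rose and 2 fell. That median was 0.29 (camera adjusted p = 0.00734; adjusted p = 0.42 with an estimated correlation), a call lost without the dimmest 50% of probe sets (adjusted p = 0.155). The unfolded protein response had a median of 0.03 (camera adjusted p = 0.364), which was -0.01 after quantile normalization. Limma's test called 0 of its 18 genes, also adjusted over the list alone, and Atf3 stood at 0.41 (adjusted p = 0.0602). Clock genes had a median of -0.08 (camera adjusted p = 0.734). Among those 16, 0 passed limma's test, also adjusted over the list alone, with Ciart at -0.52 (adjusted p = 0.0815).

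Metabolic genes of the hepatocyte leaned downward, mostly by less than 2-fold. Macrophage, monocyte and T and NK cell markers were higher in the same livers (medians 1.42, 1.57 and 0.34). Whether a smaller share of hepatocyte RNA accounts for these metabolic falls was not tested. Of 39 genes of drug metabolism the epoxygenase Cyp2c23 fell by 1.29 and the oxygenase Fmo1 rose by 0.56; adjusted over the list alone 9 fell and 1 rose. The median was -0.51 (camera adjusted p = 0.00112; adjusted p = 0.495 with an estimated correlation). Cholesterol synthesis had a median of -0.40 (camera adjusted p = 0.000322; adjusted p = 0.495 with an estimated correlation). The kinase Pmvk fell by 0.83, the sterol sensor Insig1 fell by 0.72 and the reductase Tm7sf2 fell by 0.47, which are 3 of 20, or 8 adjusted over the list alone. Amino acid and urea metabolism also stood at -0.40 (camera adjusted p = 0.000501; adjusted p = 0.495 with an estimated correlation). The histidine lyase Hal fell by 1.05 and the ornithine carrier Slc25a15 fell by 0.52, and 7 of 20 fell adjusted over the list alone.

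The liver both burns fatty acids and makes them. Fatty acid oxidation had a median of -0.25 (camera adjusted p = 0.00734; adjusted p = 0.495 with an estimated correlation). The thioesterase Acot1 fell by 1.00 and the fatty acid carrier Fabp1 fell by 0.58, while adjusted over the list alone 11 of 26 fell and 1 rose. Control replicate 3 was low in both, at 12.1 for Fabp1 against 12.5 to 12.6 in the other controls, and at 9.58 for the list's mean against 9.79 to 9.81. Lipogenesis stood at -0.33 (camera adjusted p = 0.0253; adjusted p = 0.489 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.0631). The malic enzyme Me1 fell by 1.13 and the elongase Elovl5 fell by 0.53; adjusted over the list alone 3 of 20 fell and 1 rose.

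Bile acid genes had a median of -0.32 and stayed just short of the threshold (camera adjusted p = 0.0559). The list passed as lower after quantile normalization (adjusted p = 0.0286), after centring on array medians (0.0103), without the dimmest 30% or 50% of probe sets (0.0228 and 0.00267), with array weights (0.0113) and with the replicate block (0.0194). It also passed without transgenic replicates 1 or 4 (adjusted p = 0.0283 and 0.0381) and without control replicates 2 or 3 (0.0152 and 0.0356). Besides Slco1a1, the receptor Nr0b2 fell by 0.91 and the sterol exporter Abcg5 fell by 0.72, whereas the exporter Abcc4 rose by 0.95. Adjusted over the list alone 9 of 27 fell and 3 rose. Glucose and glycogen genes had a median of -0.16 (camera adjusted p = 0.345). Limma's test called 0 of those 16, also adjusted over the list alone, with Irs1 at -0.28 (adjusted p = 0.0951). Hepatocyte transcription factors and secreted proteins had a median of -0.17 (camera adjusted p = 0.183), and passed as lower after quantile normalization (median -0.21, adjusted p = 0.0384) and without the dimmest 50% of probe sets (0.0129). Of 23, the growth hormone receptor Ghr fell by 0.75, its target Igf1 fell by 0.56 and the factor Foxa1 fell by 0.42, the same 3 as adjusted over the list alone. Fetal liver genes differed in sign between median, -0.08, and mean, 0.19, with camera's direction up (adjusted p = 0.791). Of 13 only the trefoil peptide Tff3 rose, by 2.51, also adjusted over the list alone, with 11.7 in transgenic replicate 1 and 9.57 to 9.86 in the other transgenic arrays.

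Some liver genes differ between the sexes under the control of growth hormone. Male-biased genes had the lowest median of all lists, -1.44 (camera adjusted p = 0.00632; adjusted p = 0.495 with an estimated correlation). Of 12, 5 fell, 0 rose and 7 did not pass, and 8 fell adjusted over the list alone. Besides Slco1a1, Cyp4a12a and Hsd3b5 these were the hydrolase Nudt7, which fell by 1.70, and the selenium-binding protein Selenbp2, which fell by 1.19. The controls were themselves far apart in this list, with means of 1.24, -0.96, -1.15 and 0.87 around their common mean, against -1.76, -2.26, -1.99 and -1.39 in transgenic replicates 1 to 4. Female-biased genes had a median of -0.62 (camera adjusted p = 0.361). Without the dimmest 50% of probe sets it was -1.25 and the list passed as lower (adjusted p = 0.0361). The sulfotransferase Sult1e1 rose by 2.97 (SE 0.20, adjusted p = 0.000206) and A1bg fell, while adjusted over the list alone 1 of 10 rose and 2 fell. Sult1e1 read 3.30 to 4.02 in the controls, near Xist, so the size of its rise is uncertain. Genes of the sex chromosomes did not separate the groups. Xist, transcribed from the inactive X chromosome of females, stood between 2.95 and 3.39 in all 8 arrays, with a log2 fold change of -0.24 (adjusted p = 0.156). The mean of the Y-linked Eif2s3y, Kdm5d and Uty lay between 7.10 and 7.72, and their log2 fold changes were 0.05, 0.06 and 0.25 (adjusted p = 0.809, 0.773 and 0.225).

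The transgenic livers were not alike in strength. On the first principal component, which held 71.7% of the variance, transgenic replicates 1 to 4 scored 38.4, 69.5, 8.57 and 7.07, and the controls between -35.3 and -26.0. The NF-kB list's mean rose above the controls by 1.43, 1.70, 0.87 and 0.86 in these 4 livers. Interferon-stimulated genes stood at 0.92, 1.76, 0.28 and 0.23, where control replicate 4 reached 0.21, so transgenic replicates 3 and 4 lay close to that control. Cell cycle genes stood at 0.90, 1.70, 0.63 and 0.51, with controls up to 0.23. Drug metabolism ran the other way, at -0.70, -1.16, -0.36 and -0.17. The matrix list was nearly even, at 0.50, 0.49, 0.39 and 0.49. Whether the lists differ from each other in this spread was not tested.

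**Figure D4:**
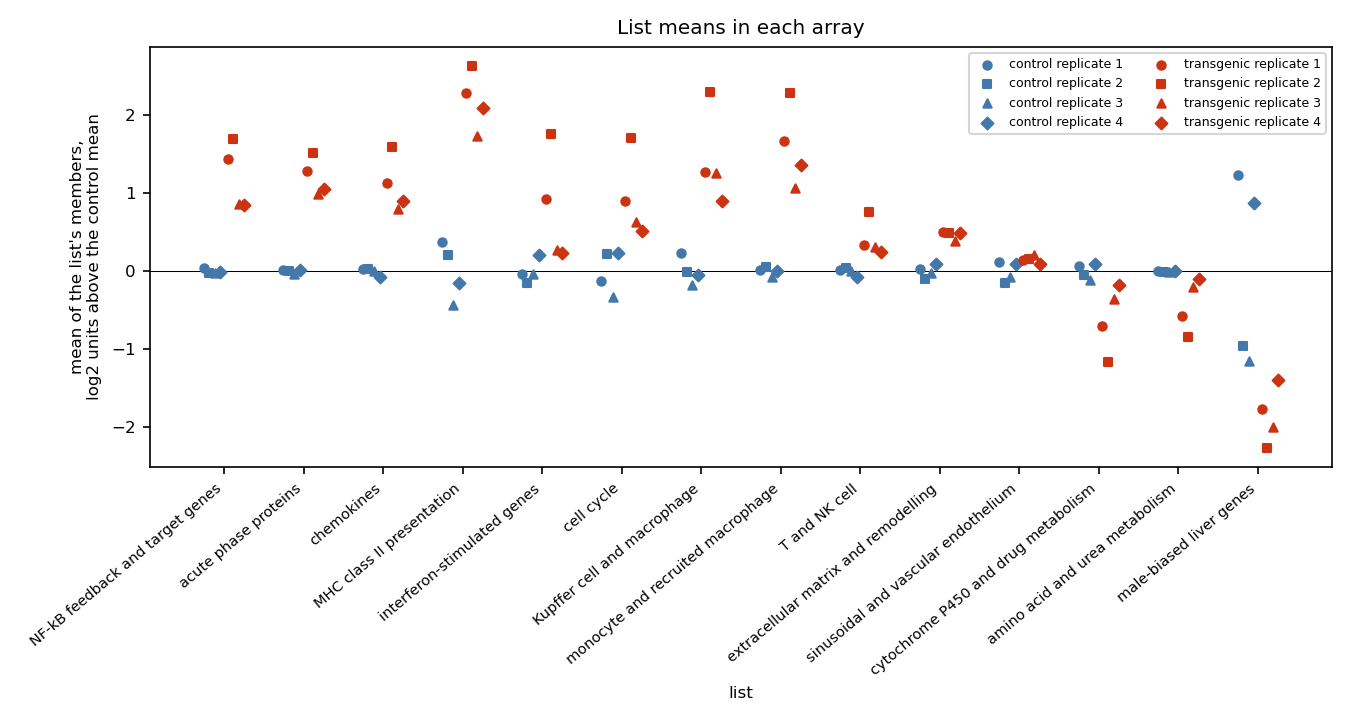
Mean of a list's members in each array, in log2 units above the mean of the controls (y axis), for 14 lists (x axis); colours are groups and marker shapes are replicate numbers. Transgenic replicate 2 is highest for the NF-kB list, at 1.70, and lowest for drug metabolism, at -1.16.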

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

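The tests on Y-linked genes, on genes of middle level, on all male-biased genes against hepatocyte genes and on fetal liver genes without Tff3 were chosen after the result was seen, and the other tests in this part before. Of the latter, the tests of dilution for the genes lower by at least 2-fold and of a less mature liver were set aside once list values were known and later taken up again unchanged. Single arrays lay far from the rest of their group by Dixon's test at 95%, which sets the gap to the nearest array against the group's range, in 12 of 278 groups examined, or 4.32%. Chance alone marks about 1 in 20 groups, so the number is no larger than chance gives. Transgenic replicate 2 accounts for 4 of the 12. It stood low for the erythroid gene Car1 (4.99 against 6.48 to 6.79, a gap of 0.831 of the range) and for the mean of the complement and coagulation list (10.1 against 10.5, gap 0.940). It stood high for the dendritic cell gene Clec9a (5.19 against 4.33 to 4.43, gap 0.876) and for the mean of the T and NK cell list (5.41 against 4.90 to 4.98, gap 0.840). The other transgenic cases were Slco1a1 in replicate 4 (5.54 against 3.46 to 3.79, gap 0.840), Tff3 in replicate 1 (11.7 against 9.57 to 9.86, gap 0.864) and the mean of the matrix list in replicate 3 (7.15 against 7.25 to 7.27, gap 0.884).

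Among the controls, replicate 1 was low for A1bg (7.51 against 9.11 to 9.42, gap 0.838). It was high for the means of the NF-kB list (6.56 against 6.490 to 6.498, gap 0.880) and of MHC class I and the immunoproteasome (8.55 against 8.40 to 8.42, gap 0.844). Control replicate 3 was low for Fabp1 (12.1 against 12.5 to 12.6, gap 0.882) and for the mean of fatty acid oxidation (9.58 against 9.79 to 9.81, gap 0.902). Outside the genes analysed, 87 probe sets without a single gene symbol were higher in transgenic liver and 32 lower, among 13767 of them. Which transcripts they read was not examined.

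For the number of called genes the real split was the only 1 of 35 with as many, its 1265 genes against 0 in the highest of the others. That share is the smallest that 35 splits allow, so grouping by chance is made less likely but is not excluded. The other splits also mix arrays of both groups, so the group difference adds to their spread and keeps their called genes few. For the lists the splits cannot decide, and chance is not excluded. With the real one, 4 of 35 splits gave at least 25 lists, the highest other 27. The split of transgenic replicates 1, 2 and 4 with control replicate 2 gave 27 and keeps much of the group difference. Its lists therefore do not show what chance alone gives.

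More genes rose than fell by at least 2-fold, 485 against 34. Differences in scale left between the deposited arrays are argued against. The ratio of higher to lower genes was 14.3 as deposited and stayed at 9.5 or more under both other scalings. What the unknown normalization before deposit did to this ratio could not be tested, since rescaling the deposited values does not undo it. Compression of bright hepatocyte transcripts cannot be told apart from a true excess over all genes. The planned ratio of 26.1 among genes with a control mean of at most 9 (470 against 18) says nothing, because for 72.2% of those genes a 2-fold fall would end under the median of all values, and brighter genes gave 15 against 16. Among the 3975 genes whose mean over all arrays lies between 7 and 9 the ratio was 17.5 (175 against 10), so at that level compression is argued against.

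The falling genes may reflect a smaller share of hepatocyte RNA in the sample, which would lower all hepatocyte transcripts alike. Hepatocyte list members with a control mean under 12 had a median of -0.28 (interquartile range 0.57, 12 members), which is 1.28 above the median of -1.56 of the 34 genes lower by at least 2-fold. Because the 34 were chosen for falling by at least 2-fold, such a gap was close to fixed beforehand, and it does not decide the question. The values do show that none of the 12 hepatocyte members fell by 2-fold, the lowest standing at -0.75. Dilution could add to the falls of the 34 genes, since the whole hepatocyte list passed as lower after quantile normalization, at a median of -0.21.

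The fall of male-biased genes, a median of -1.44 over all 12, was weighed against dilution, sex and a less mature liver, while growth hormone is treated with the other observations. Dilution as the whole cause is made less likely but is not excluded. The mean of all male-biased members fell further than that of the hepatocyte members. The difference was -1.60 with a 95% interval from -3.03 to -0.18. An exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 arrays allow. The male-biased list had the lowest median of all lists in these same arrays, and this test was chosen after that was seen. Neither the interval nor the p is adjusted for that choice. More females among the transgenic mice is argued against by the Y-linked genes. Their mean differed by 0.12 with a 95% interval from -0.23 to 0.46. In all 8 arrays Xist read 2.95 to 3.39 and the Y-linked mean 7.10 to 7.72, the pattern of males in both groups. A less mature liver cannot be told apart from an effect of the kinase. The mean of fetal liver genes differed by 0.19 (95% interval 0.03 to 0.36, past the bound of 0.25 set for it). Tff3 carries this difference, and the other 12 genes differed by 0.00145 (-0.21 to 0.22). The list holds genes of fetal liver only, so a delay at later stages of maturation was not tested.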

How the results depend on the processing

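All alternatives in this part were planned. Of the 1265 calls, 0 turned to the other direction in a setting that tested them. Of the 87 called genes named in the text, 23 kept their calls in every setting, and 4 others did in all but the filter on the dimmest 50%, which leaves them out.

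Counts were most sensitive. Higher genes fell to 618 with centring on array medians, 425 with all probe sets tested and 271 with treat. Lower genes became 638 with quantile normalization, 97 with centring, 54 with all probe sets, 501 with array weights and 8 with treat. At 2-fold, treat left 255 higher and 8 lower, and the lower ones were 17 with centring and 12 with all probe sets. Treat asks for more than a change from 0, and testing all probe sets adds tests; for the others the cause was not tested.

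The replicate number as a block gave 670 higher and 174 lower genes, with 705 of its 844 calls shared with the 1265. Whether the numbers pair the animals is not given in the sources used here. Residuals of same-numbered arrays correlated at 0.278, -0.030, 0.274 and -0.125. For 2 transgenic arrays the control with the highest correlation was that of the same number. These values do not settle the question.

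Leaving out 1 array in turn gave 192 (without control replicate 2) to 1636 (without transgenic replicate 4) higher genes and 3 (without transgenic replicate 1) to 944 (without transgenic replicate 4) lower ones. At 2-fold the ranges were 162 to 670 and 2 to 105, between the same arrays. Named genes lost their calls most often without transgenic replicate 1 (55 of 87) and without control replicates 1, 2, 3 or 4 (49, 55, 52 and 50), against 12, 4 and 0 without transgenic replicates 2, 3 or 4.

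With an estimated correlation camera called 0 lists higher and 0 lower, against 18 and 7; fry called 12 and 2. Fewer list members remain without dim probe sets, and some lists not called in the main setting then turned in camera's direction. Without the dimmest 30% the medians were -0.17 for neutrophils, -0.0719 for B and plasma cells and 0.0708 for mast cells. Without the dimmest 50% they were -0.0138 for the unfolded protein response and 0.15 for erythroid genes. The direction for fetal liver genes turned down when genes of more than 1 list were left out (median -0.10) and without control replicate 1 (-0.10; range -0.12 to -0.0274). Clock genes turned without control replicate 1 (-0.06; range -0.17 to -0.0311), and B and plasma cells without control replicate 4 (-0.08; range -0.0941 to -0.0210). The cause was not tested.

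Signal over background cannot be judged from these values, so for dim genes an absent change is not told from an unread one. The size of a rise or fall that starts or ends at a dim level is uncertain for the same reason.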

Other observations

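The gene families below were chosen after the values were seen. Genes were grouped by the stem of their symbols, which gave 618 families with at least 5 members. Camera at the preset correlation called 55 higher and 19 lower, but 0 with an estimated correlation, so they are described by their members. Toll-like receptors, which sense microbial and tissue damage, were higher in 6 of 10 members with a median log2 fold change of 1.36. That number was 8 after quantile normalization and 4 with arrays centred on their medians. Guanylate-binding proteins, GTPases of the interferon response, were higher in 6 of 8 with a median of 1.99, and in 6 under both other scalings. Of the Mcm family, whose core members form the helicase of DNA replication, 6 of 10 were higher with a median of 0.92, and 5 with centred arrays. In all 3 families 0 members fell under any scaling.

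A hypothesis was that lower growth hormone signalling lies behind the fall of male-biased genes, as the growth hormone receptor Ghr fell by 0.75 and Igf1 fell by 0.56. The prediction, set before its value was seen, was that Socs2, a gene that growth hormone induces and that stands in no list, would be lower. It was not: its log2 fold change was 1.21 (adjusted p = 0.121), with a 95% interval from 0.13 to 2.29, above the bound of -0.25 set for it. The value rests partly on control replicate 2, without which it was 0.72 (-0.07 to 1.502), and over the arrays left out in turn the lowest bound was -0.17. A dimmer probe set of Socs2 stood at 0.51 (0.11 to 0.90). Transgenic replicates 1 to 4 read 8.16, 8.69, 8.41 and 8.20, and the controls 6.70, 5.68, 8.33 and 7.91. Inflammatory cytokines also induce members of the Socs family, so a weaker growth hormone signal could still be present behind a Socs2 raised by other routes, which was not tested.

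A further hypothesis was that normalization widened the spread of the transgenic arrays, whose SD on the first principal component was 6.03 times that of the controls. The ratio was 7.41 after quantile normalization and 4.73 after centring on array medians, both above the bound of 2 set before. This argues against differences in scale left between the deposited arrays. An effect of the unknown normalization before deposit could not be tested in this way. A difference between the animals in how strongly the transgene acts, or in the stage of inflammation, stays open and was not tested.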
